A study of Mus musculus domesticus x Mus spretus and Mus musculus domesticus and Mus spretus with 89 samples.

How the data were processed

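Polyadenylated RNA of the hypothalamus was sequenced as 150-base read pairs in 89 mice, 1 library per mouse, covering dom (WSB/EiJ), spret (SFM/Pas) and hybrids of a dom mother and a spret father at E17.5 and postnatal days 21 and 71. The deposited values are 1 signal per gene and library, which the authors made by dividing counts by 1 size factor per library. The submitters' processing notes name GRCm38, StringTie 1.3.3, SAMtools 0.1.19, DESeq and DESeq2 1.16.1. The aligner and the gene annotation are not given in the sources used here. Of the 30093 genes listed, 30087 identifiers were found in GENCODE M21 on the same chromosome, from which positions were taken, and 6 pseudoautosomal genes were left out of the X-linked genes. Samples are named by genotype, age, sex and litter. Litters come from the sample labels, and the labels carry no batch, lane or date.

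The size factors were read from the spacing of the values, which gave whole counts for 100% of values in each library (tolerance 0.05 of a count). Values between 1 and 24 piled up at 6 counts (4, 8, 12, 15, 19 and 23), which held 59.2% of them against 25% if evenly spread, so 1 sequenced fragment stands for about 4 counts. Total counts ranged from 57632862 to 63413768 with a median of 62265291, apart from 1 library with 6514390. Because of the step of 4, counting error is larger than the totals imply. Libraries of the same group were compared for copies: the lowest chi-square per gene, in units of 4 counts, was 5.79 over 177 pairs, and 0 pairs were identical.

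Normalised values were analysed as log2 of the value plus a pseudocount of 1, over genes with a mean of at least 10 in at least 1 group. Each age had its own fit with limma 3.58.1 (lmFit, contrasts.fit and eBayes with a trend) and 1 mean for each of 6 groups of genotype and sex. Changes with age came from 1 fit of all 18 groups. The contrasts were dom minus spret, hybrid minus the mean of the parents' log2 means, male minus female, and the difference between the sexes in the hybrid departure, with Benjamini-Hochberg adjusted p below 0.05. A gene was transgressive when a hybrid group was above or below both parents of its sex in both tests. Fisher's exact test compared X-linked with autosomal genes. Because both tests share the hybrids, transgressive counts were set against separate hybrids for each test (every division of a group, 6 or 20) and 20 simulations without a hybrid effect. The position of each hybrid is the slope of its departure from mid-parent on the parents' distance from it, over genes called between dom and spret. An exact 2-sided permutation test compared positions between the sexes, with Benjamini-Hochberg values over 6 comparisons.

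Gene lists written from general knowledge before the data were examined were tested by camera with the preset correlation of 0.01 and again with an estimated one, adjusted over 30 lists in each of 11 comparisons. The 3 imprinted lists were also tested against mid-parent in each sex. The lists are paternally expressed, maternally expressed and tissue-dependent imprinted genes, genes that escape X inactivation, Y-linked genes, neuropeptides, hormone and neuropeptide receptors, steroid receptors and enzymes, and hypothalamic transcription factors. Markers were listed for neurons, proliferation, oligodendrocytes and their precursors, astrocytes, ependyma and tanycytes, microglia, endothelium, fibroblasts, choroid plexus, pituitary, thalamus, striatum, and cortex and hippocampus. The others are red blood cell, immediate early, heat shock and stress, interferon-stimulated and antigen presentation, mitochondrially encoded, respiratory chain and synaptic genes. A marker score is the mean of the centred log2 values of a list in a library. Scores were set against 100 random lists matched gene by gene on expression, and 100 matched also on the standardised difference between hybrid and parent males (1 of the 20 nearest genes).

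The comparisons, the alternatives except those with litters left out or marker scores and the rule for named genes were also fixed before the data were examined. The rule took, at each age, the 5 highest and 5 lowest fold changes between the parents and against mid-parent among called genes with a mean of at least 100 and no overlap between animals. It further took the 4 highest and 4 lowest transgressive genes per age and sex, the 4 leading X-linked ones and every imprinted one. For sex differences it took the 4 autosomal and 4 X-linked genes with the lowest p, for age steps the 5 highest and 5 lowest, for differences of differences the 4 with the lowest p, and of each list up to 4 members with the lowest p. Genes with numbered placeholder names were counted but not named. Transgressive genes shared by the sexes in juveniles were chosen after their values were seen.

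The alternatives fixed in this way were a pseudocount of 8, no filter, quantile normalisation, edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 on the whole counts, litter as a random block (duplicateCorrelation) or as a fixed effect, a minimum fold of 1.5, each sex alone, a background of genes with a mean of at least 100 for the X chromosome, 4 animals per group in 20 draws, and leaving out each library in turn. Random splits, 100 for each count with the real one included, shuffled genotype within each sex, sex within each genotype or age within each genotype and sex. Further splits swapped only the sexes of siblings. In 100 draws, the real one included, residuals of whole litters were exchanged between litters of the same make-up within an age. They were scaled by the square root of n/(n - 1) and added to group means with dom equal to spret, hybrids at mid-parent, or hybrids moved to the nearer parent where they lay beyond both. These draws, the other lists in each sex, the lists in the interaction and list tests without 1 library or on moderated statistics (cameraPR) were chosen after the results were seen. The tests were also run on simulated data, in which 100 genes were changed 2-fold. Of these limma recovered 72 in males and 65 in females of embryos, and 37 and 33 at 1.5-fold. A position set to 0.5 was recovered as 0.432 to 0.466, so positions are underestimated. Work was done in R 4.3.3 with the data.table package (1.17.8) and in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9. Allele-specific expression and sequence variants cannot be had from the table and were not analysed here.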

Results

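Polyadenylated RNA of the hypothalamus, the brain region that governs hormone release, feeding and body temperature, was sequenced from 89 mice. The mice were Mus musculus domesticus (WSB/EiJ, here dom), Mus spretus (SFM/Pas, here spret) and their hybrids, which had a dom mother and a spret father. Hybrid males therefore carried a dom X chromosome, and all hybrids inherited dom mitochondria. The ages were late embryonic (E17.5, 29 mice from 15 litters), postnatal day 21 (30 juveniles, 17 litters) and postnatal day 71 (30 adults, 17 litters). Of the 18 groups of genotype, age and sex, hybrid embryo females and spret juvenile females had 4 mice, hybrid juvenile males had 6 and the others had 5. The labels give litters, and 14, 13 and 13 litters contributed a male and a female. Total counts per library ranged from 57632862 to 63413768, except for a hybrid embryo male of litter 20 with 6514390, called the shallow library. Levels are normalised counts with standard deviations, fold changes are on the log2 scale with standard errors, and every named fold change had an adjusted p below 0.05 unless stated.

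The genes of the sex chromosomes separated males from females in every group. Xist, the RNA that silences an X chromosome in females, averaged between 7023 ± 2541 (dom adults, n = 5) and 22141 ± 5721 (spret juveniles, n = 4) in the 9 female groups. In the 9 male groups its highest mean was 37.5 ± 28.9 (spret juveniles, n = 5). The Y-linked RNA helicase Ddx3y averaged 2536 ± 358 or more in each male group and 32.9 ± 18.2 or less in each female group.

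The comparison of dom with spret asked how far the parental species differ. Pnma2, a gene of the paraneoplastic antigen family on chromosome 14 (66911170 to 66921023, GRCm38), was higher in dom embryos by 9.78 ± 0.47. Its embryo level was 3477 ± 323 in dom (n = 10), 2088 ± 211 in hybrids (n = 9) and 6.27 ± 7.32 in spret (n = 10), and the juvenile and adult differences were 7.81 ± 0.26 and 8.90 ± 0.35. The zinc finger gene Zfp984 was higher in dom by 7.99 ± 0.31, 6.88 ± 0.27 and 6.96 ± 0.35 at the 3 ages. Zfp738 was higher in spret (-6.45 ± 0.37 in embryos, -6.83 ± 0.41 in adults), and so were Adam32, of a family of membrane proteases (-6.11 ± 0.41 in embryos), Ccdc63 (-7.51 ± 0.45 in juveniles) and the cytochrome P450 gene Cyp4f37 (-6.83 ± 0.34 in juveniles). In adults Spesp1, which encodes a protein of the sperm acrosome, stood at 524 ± 112 in spret and 0.764 ± 2.42 in dom. Among hypothalamic neuropeptide genes, the wake-promoting Hcrt was higher in dom embryos by 3.11 ± 0.36, and in juveniles Avp, the antidiuretic hormone gene, was higher in dom by 2.11 ± 0.17 and Ghrh, which drives growth hormone release, by 2.18 ± 0.21.

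By limma, 7331 of 17397 genes differed between the parents in embryos (3869 higher in dom), 9354 of 17585 in juveniles (4680 higher in dom) and 9183 of 17591 in adults (4745 higher in dom). Mitochondrially encoded genes differed as a set in embryos and adults: 6 of 10 were higher in dom embryos and 2 in spret, led by mt-Cytb, a subunit of complex III, at 4.34 ± 0.11. All 8 were called when adjusted over the list alone (camera adjusted p = 0.0367, and 0.962 with an estimated correlation). In adults 7 were higher in dom and 2 in spret, 9 adjusted over the list alone (adjusted p = 0.00563, and 0.977 with an estimated correlation). In juveniles 7 were higher in dom and 2 in spret, and the list was not called (adjusted p = 0.0629). Nuclear-encoded respiratory chain genes were lower in dom adults, with 14 of 28 lower, 1 higher and 15 called when adjusted over the list alone (adjusted p = 0.0182, and 0.977 with an estimated correlation). Of these, Ndufb8 differed by -0.77 ± 0.09 and Sdhb by -0.49 ± 0.09, whereas the X-linked Ndufa1 was higher in dom by 0.91 ± 0.11. The files hold no allele or mismatch information, so spret reads that failed to match the reference genome cannot be told from lower expression.

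The comparison of hybrids with the mid-parent value, the mean of the parents on the log2 scale, asked which genes depart from that midpoint. In embryos Pnma2 lay above mid-parent by 4.15 ± 0.43 (120% of the arithmetic mean of the parents, 106% in juveniles and 108% in adults), the mitochondrial mt-Co2 by 5.22 ± 0.70 and mt-Cytb by 2.22 ± 0.10. The synaptic vesicle calcium sensor Syt1 lay above by 0.73 ± 0.11, Ghrh by 0.83 ± 0.22, the neuropeptide gene Tac1 by 0.47 ± 0.13 and the synaptic vesicle gene Syp by 0.35 ± 0.09. Below mid-parent lay the acetyltransferase-family gene Nat8f4 (-1.43 ± 0.27), the ketone body enzyme Hmgcs2 (-0.76 ± 0.20), the matrix protein gene Cyr61 (-0.76 ± 0.17), the GTPase Rac2 of blood and immune cells (-0.68 ± 0.18), Sertad3 (-0.63 ± 0.16) and the pericyte receptor Pdgfrb (-0.42 ± 0.10). Over the alternatives, leaving out each library included, the calls of Hmgcs2 and Tac1 held in 13 of 37, that of Ghrh in 18 and that of Rac2 in 20. By limma 372 genes departed from mid-parent, 287 above and 85 below, and 183 did so with litter as a random block. The count was 243 without the hybrid female of litter 10, 242 without that of litter 19 and 627 without that of litter 9.

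Several cell-type lists shifted together in hybrid embryos. All 14 proliferation and progenitor markers lay below mid-parent (median -0.39), 0 called by limma over all genes and 11 adjusted over the list alone (camera adjusted p = 3.46e-08, and 0.305 with an estimated correlation). All 9 meningeal and vascular fibroblast markers lay below (median -1.94), with Pdgfrb the 1 called over all genes and 9 adjusted over the list alone (adjusted p = 3.39e-07, and adjusted p = 0.431 with an estimated correlation). The 11 microglia markers were also below (median -0.33), with 0 called on either basis (adjusted p = 0.00273, and 0.561 with an estimated correlation). Synaptic genes lay above in 20 of 20 cases, 2 called and 4 adjusted over the list alone (adjusted p = 9.03e-07). Of 31 neuropeptide genes 25 lay above, 2 called and 6 adjusted over the list alone (adjusted p = 0.00198). Of 26 hormone and neuropeptide receptors 24 lay above, 0 called on either basis (adjusted p = 0.000532), and these 3 lists had adjusted p = 0.466 with an estimated correlation. Of 14 neuron markers 12 lay above, with Syt1 called on either basis (adjusted p = 0.00198, and 0.587 with an estimated correlation). Mitochondrial genes were above in 6 and below in 2 of 10 cases, 8 adjusted over the list alone (adjusted p = 1.4e-10, and adjusted p = 0.0492 with an estimated correlation).

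These lists were then tested by sex. In hybrid embryo males proliferation markers had a median of -0.64 (6 called, 11 adjusted over the list alone, adjusted p = 9.18e-09, and adjusted p = 0.227 with an estimated correlation) and fibroblast markers of -3.15 (4 called, 9 adjusted over the list alone, adjusted p = 9.06e-08, and adjusted p = 0.373 with an estimated correlation). Synaptic genes (median 0.36), neuron markers (0.30), neuropeptides (0.25), receptors (0.38) and microglia markers (-0.49) had adjusted p = 9.18e-09, 0.000168, 0.0013, 0.000315 and 0.000706 in males, and adjusted p = 0.464 each with an estimated correlation. In hybrid embryo females proliferation markers had a median of -0.13 (13 of 14 below) and fibroblast markers of -0.72 (9 of 9 below), with 0 called on either basis (adjusted p = 0.0405 for both, and adjusted p = 0.746 with an estimated correlation). Without the hybrid female of litter 19 these medians were 0.02 and -0.06 (adjusted p = 0.896 and 0.853), and without that of litter 9 -0.27 and -1.63. The other 5 lists were not called in females (medians 0.04, 0.05, 0.11, 0.13 and -0.15, adjusted p = 0.309, 0.432, 0.201, 0.149 and 0.379). Mitochondrial genes were called in both sexes (6 of 10 above and 8 adjusted over the list alone in each, adjusted p = 9.06e-08 and 4.56e-16, and 0.219 in males and 0.00625 in females with an estimated correlation).

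In juvenile hybrids the neuropeptide gene Npw lay below mid-parent by -1.83 ± 0.27, the ceramidase gene Acer2 by -1.05 ± 0.17, the stress-induced kinase Sgk1 by -1.01 ± 0.19, the cell cycle inhibitor Cdkn1a by -0.89 ± 0.20 and the dendritic protein gene Map2 by -0.46 ± 0.09. Pnma2 lay above by 3.00 ± 0.22, Ccdc63 by 2.66 ± 0.37, the imprinted thyroid hormone deiodinase Dio3 by 1.04 ± 0.26 and Syt1 by 0.69 ± 0.11. By limma 895 genes departed from mid-parent (589 above, 306 below), and 573 with litter as a random block. Mitochondrial genes were above in 7 and below in 2 of 10 cases, 9 adjusted over the list alone (adjusted p = 0.000319, and 0.869 with an estimated correlation). Oligodendrocyte markers lay above in 12 of 13 cases, with 0 called on either basis (adjusted p = 0.028, and adjusted p = 0.869 with an estimated correlation). By sex, 2 lists were called in males in every fit without 1 library, mitochondrial genes (median 1.06, 5 called, 9 adjusted over the list alone, adjusted p = 7.39e-06, and adjusted p = 0.748 with an estimated correlation) and heat shock and stress genes (-0.24, from -0.40 to -0.10 without 1 library, 1 called, 2 adjusted over the list alone, adjusted p = 0.00379, and adjusted p = 0.814 with an estimated correlation). In females oligodendrocyte markers were (0.28, from 0.19 to 0.38 without 1 library, 0 called on either basis, adjusted p = 0.00176, and adjusted p = 0.927 with an estimated correlation). Neuropeptides, thalamus markers and paternally expressed genes in males and mitochondrial genes in females were called in 28, 23, 28 and 24 of 30 such fits, and not with an estimated correlation (adjusted p from 0.748 to 0.927). The thalamus call was lost, among others, without the male of spret litter 17, which had high thalamus markers.

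Adult hybrids departed from mid-parent at 2538 genes by limma, 1563 above and 975 below. Pnma2 lay above by 3.57 ± 0.30 and the antisense transcript Lrp8os2 by 2.45 ± 0.36. Acer2 lay below by -0.95 ± 0.11, mt-Co1 by -0.81 ± 0.10, the antiviral gene Rsad2 by -0.78 ± 0.16, the anion transporter Slco1a4 of brain vessels by -0.75 ± 0.15 and the vessel growth factor Angpt2 by -0.71 ± 0.13. Of 25 hypothalamic transcription factors 21 lay above, 3 of them called and 5 adjusted over the list alone (adjusted p = 0.0371, and adjusted p = 0.769 with an estimated correlation). The called members were Nkx2-1, which patterns the ventral hypothalamus (0.74 ± 0.14), Otp, of the neuroendocrine lineages (0.34 ± 0.09), and Arx (0.40 ± 0.10). Astrocyte markers lay below in 8 of 10 cases, 3 called, among them the water channel Aqp4 (-0.41 ± 0.11), and 4 adjusted over the list alone (adjusted p = 0.0459, and adjusted p = 0.769 with an estimated correlation). Endothelial markers lay below in 7 of 8 cases, 3 called and 5 adjusted over the list alone (adjusted p = 0.0459, and adjusted p = 0.769 with an estimated correlation). Respiratory chain genes lay below in 24 of 28 cases, 3 called below, 2 above and 7 adjusted over the list alone (adjusted p = 0.0371, and adjusted p = 0.891 with an estimated correlation). By sex, transcription factors were called in males in every fit without 1 library (median 0.31, 2 called, 3 adjusted over the list alone, adjusted p = 0.00567, and adjusted p = 0.812 with an estimated correlation). Also called in males were respiratory chain genes (1 called above, 0 below), lost without the spret male of litter 4, and red blood cell genes, lost in 6 of 30 fits, among them that without the hybrid male of litter 19, whose litter had them low. In females heat shock and stress genes (median 0.37, against -0.05 in males) were called in 29 of 30 fits, oligodendrocyte, astrocyte and endothelial markers in 19, 15 and 18 and mitochondrial genes in 16. With an estimated correlation these had adjusted p from 0.635 to 0.812.

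The adult count was sensitive to litter: 958 genes were called with litter as a random block and 599 without both hybrids of litter 19. It was 1207 without the hybrid male and 1497 without the hybrid female of litter 19, and 1633, 1682 and 1600 without the hybrid males of litters 12 and 14 and the hybrid female of litter 13. Genes above mid-parent were shared between ages beyond the number expected if independent, with 156 shared by embryos and juveniles (expected 9.05) and 299 by juveniles and adults (expected 53.1). For genes below mid-parent 12 were shared by embryos and juveniles (expected 1.51) and 22 by juveniles and adults (expected 17.0). The mid-parent value used here is that of the logarithms: of the genes above it, 240 of 287 in embryos, 466 of 589 in juveniles and 1425 of 1563 in adults also exceeded the arithmetic mean of the parents. Of those above, 200, 362 and 400 had parents over 4-fold apart (153, 242 and 263 over the arithmetic mean), and 51, 143 and 1042 parents within 2-fold, all over it.

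Each hybrid's position was measured as a log2 slope over genes that differ between dom and spret, where 1 is the dom level, 0 the mid-parent and -1 the spret level. Genes furthest apart weigh most, and most genes may lie elsewhere. X-linked genes of hybrid males lay near the dom level, at 0.760 ± 0.101 in embryos (SD, n = 5), 0.860 ± 0.173 in juveniles (n = 6) and 0.924 ± 0.0826 in adults (n = 5). Those of hybrid females lay at 0.283 ± 0.213 (n = 4), 0.284 ± 0.230 (n = 5) and 0.361 ± 0.204 (n = 5). The exact 2-sided permutation p was 0.00794, 0.00433 and 0.00794, over 216, 264 and 261 genes, and the Benjamini-Hochberg adjusted p over 6 comparisons was 0.0159 at each age. Autosomal genes lay at 0.137 ± 0.135 in embryo males and 0.219 ± 0.0217 in embryo females, at 0.154 and 0.142 in juveniles and at 0.181 and 0.168 in adults. The exact permutation p for autosomes was 0.270, 0.258 and 0.389, where the smallest possible p is 0.00794, 0.00216 and 0.00794.

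**Figure D1:**
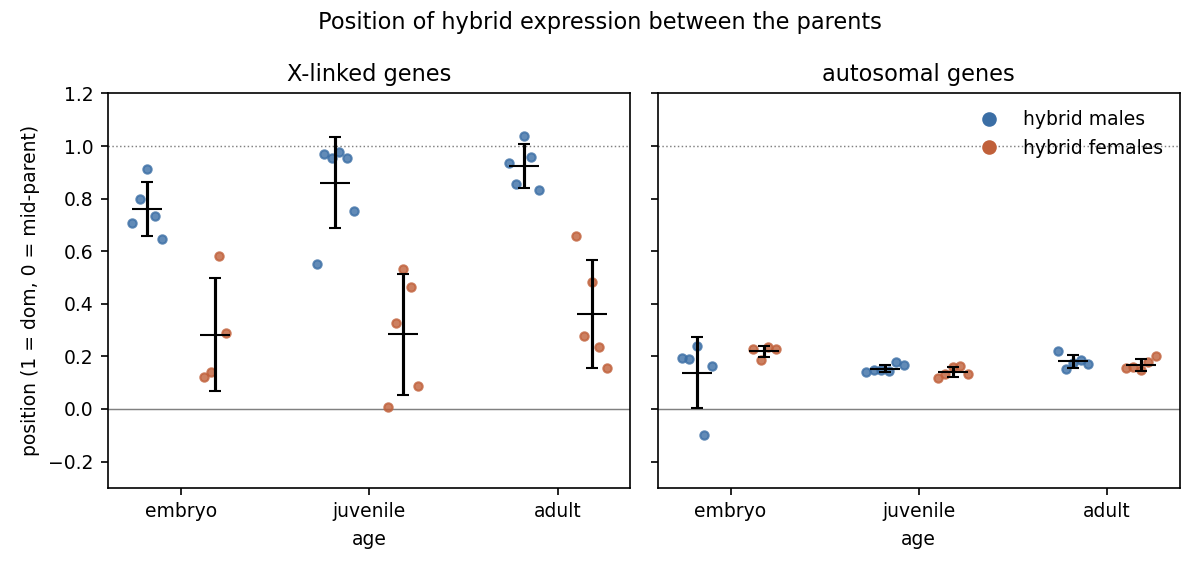
Position of X-linked and autosomal expression between the parents in each hybrid, by age and sex (1 is the dom level, 0 the mid-parent, -1 the spret level). Points are animals, and bars are means with standard deviations.

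Transgressive genes, those significantly above or below both parents of the same sex, were counted to ask whether hybrid males are affected more than females. In embryo males the Avp gene on chromosome 2 (130580620 to 130582554) was higher than in dom by 1.00 ± 0.31 and than in spret by 1.11 ± 0.31, with means of 7373 ± 1975 in hybrids, 3854 ± 1622 in dom and 3388 ± 724 in spret (n = 5 each). The nuclear envelope gene Syne1 (0.79 ± 0.24 and 0.77 ± 0.24 against dom and spret), the X-linked Nhsl2 (0.76 ± 0.20 and 1.02 ± 0.20) and the sulfonylurea receptor gene Abcc8 (0.73 ± 0.23 and 0.66 ± 0.23) were also above both parents. The calls held in 13 of 38 alternatives for Avp, 25 for Syne1, 34 for Nhsl2 and 8 for Abcc8, which was reversed in 1. Genes below both parents included genes of connective tissue: the collagen crosslinking enzyme Lox (-4.33 ± 1.13 and -3.96 ± 1.13), the collagen gene Col3a1 (-3.30 ± 1.01 and -3.01 ± 1.01) and the mesenchymal transcription factor Twist1 (-3.18 ± 0.87 and -2.81 ± 0.87), together with Vamp5 (-3.25 ± 0.79 and -3.02 ± 0.79). These held in 31, 18, 30 and 35 of 38 alternatives, Col3a1 being reversed in 1. Hybrid embryo males had a mean fibroblast marker score of -1.47 ± 1.86 (-0.665 ± 0.520 without the shallow library), against 1.53 ± 1.12 in dom and 0.896 ± 1.85 in spret males, and a proliferation marker score of -0.358 ± 0.168, against 0.177 ± 0.204 and 0.253 ± 0.269. In embryo females Mapk6, a protein kinase gene, was above both parents (0.72 ± 0.14 and 0.87 ± 0.14), as it was in embryo males and in adult females (0.70 ± 0.17 and 0.68 ± 0.17).

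By limma 161 genes were transgressive in embryo males, 22 above and 139 below, and 2 in embryo females, 1 in each direction. Without the shallow library the counts were 83 (25 above, 58 below, 53 of them among the 161) and 2. The male count was 96 without the spret male of litter 6, 52 without the dom male of litter 15 and 59 without that of litter 16. It was 35 when the male libraries were fitted alone, 3 with the fibroblast score and 0 with the proliferation score in the fit, where limma at an unadjusted p below 0.05 called 84 genes and the same threshold without the score called 882. DESeq2 called 325 and 8 genes in males and females, and edgeR 149 and 2. Both comparisons share the hybrids: 109 and 14.6 genes would be expected if the comparisons were independent, and 0 were called in simulations without a hybrid effect. With separate hybrids for each the median was 8 (0 to 41) and 0 (0 to 1). For the excess of 159 in males chance was not excluded by random splits of the animals by sex, the highest of which gave 493, whereas swaps of sex within litters gave at most 90. Exchanging the residuals of whole litters gave as many male genes and as large an excess in 11 of 100 draws (male median 17, up to 509, against 0 simulated), so chance was not excluded for either.

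In juvenile males the cysteine protease gene Ctsc was above both parents (0.53 ± 0.13 against dom, 0.84 ± 0.13 against spret), as were Pbx4, a homeobox gene (0.44 ± 0.12 and 0.84 ± 0.12), and the X-linked Ldoc1 (0.72 ± 0.23 and 0.81 ± 0.23). Below both were Npw (-1.38 ± 0.44 and -2.85 ± 0.44), Sgk1 (-1.13 ± 0.31 and -0.93 ± 0.31), the lipid enzyme gene Mboat2 (-0.87 ± 0.27 and -0.79 ± 0.27) and Clcn4, a chloride and proton exchanger gene (-0.91 ± 0.09 and -0.81 ± 0.09). Juvenile females had Ctsc (0.67 ± 0.14 and 0.68 ± 0.15), Pbx4 (0.54 ± 0.12 and 0.95 ± 0.13), the squalene synthase gene Fdft1 (0.48 ± 0.10 and 0.52 ± 0.10) and the X-linked Gnl3l (0.37 ± 0.11 and 0.47 ± 0.12) above both parents. Below both they had the hypoxia factor gene Hif3a (-1.64 ± 0.53 and -1.82 ± 0.56), the collagen gene Col5a3 (-0.76 ± 0.25 and -1.03 ± 0.26), the glucocorticoid-responsive Klf9 (-0.78 ± 0.18 and -0.57 ± 0.20) and Zfp276 (-0.51 ± 0.13 and -0.46 ± 0.14). The call of Col5a3 held in 11 of 38 alternatives. Ctsc, Pbx4 and Xkr6 were transgressive in the same direction in both sexes (0.0139 expected by chance). The totals were 17 in males (4 above, 13 below) and 23 in females (6 above, 17 below).

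In adult males AY036118, the cell surface gene Tacstd2 (1.64 ± 0.32 and 0.92 ± 0.32), the cytokine receptor gene Csf2ra (0.87 ± 0.26 and 1.10 ± 0.26) and the cytochrome oxidase subunit Cox6a2 (0.73 ± 0.23 and 0.70 ± 0.23) were above both parents. Clcn4 (-0.99 ± 0.12 and -1.06 ± 0.12), Acer2 (-1.40 ± 0.18 and -0.99 ± 0.18), Angpt2 (-0.86 ± 0.21 and -0.97 ± 0.21) and the vesicle adaptor gene Ap3m1 (-1.01 ± 0.25 and -0.84 ± 0.25) were below. Adult females had AY036118 (1.18 ± 0.29 and 1.31 ± 0.29), Mapk6, the endoplasmic reticulum gene Sdf2l1 (0.65 ± 0.21 and 0.68 ± 0.21) and Crhbp, which binds corticotropin-releasing hormone (0.69 ± 0.20 and 0.61 ± 0.20), above both. The protease gene Senp8 (-1.12 ± 0.33 and -0.96 ± 0.33), the vasoconstrictor gene Edn1 (-0.98 ± 0.26 and -0.87 ± 0.26), the X-linked microglial receptor Gpr34 (-0.95 ± 0.27 and -0.83 ± 0.27) and Rsad2 (-0.89 ± 0.25 and -0.79 ± 0.25) were below. The call of Sdf2l1 held in 17 of 38 alternatives. The totals were 27 in males (14 above, 13 below) and 41 in females (11 above, 30 below).

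With separate hybrids medians were 2 and 4 in juvenile males and females and 3 and 0.5 in adults. Simulations called 0, but litter exchanges a median of 11, 16, 8 and 4. DESeq2 called 26, 38, 51 and 70 and edgeR 17, 17, 29 and 42. The male count exceeded the female count by -6 in juveniles and -14 in adults, and random splits by sex gave differences of up to 145 and -1452, so chance was not excluded. The juvenile male count of 17 was 10, 7 and 10 without the dom males of litters 10, 11 and 5, 11 without the spret male of litter 14, and 6, 11 and 9 without the hybrid males of litters 1, 2 and 4. The juvenile female count of 23 was 14 without the dom female of litter 11, 15 without the spret female of litter 12, and 12, 14 and 45 without the hybrid females of litters 1, 2 and 6. The adult male count of 27 was 61, 16, 17 and 12 without the hybrid males of litters 10, 14, 15 and 19, 13 and 69 without the spret males of litters 3 and 7, and 16 and 14 without the dom males of litters 5 and 6. The adult female count of 41 was 20, 19 and 18 without the hybrid females of litters 12, 13 and 19, and 94, 17 and 20 without the dom females of litters 18, 5 and 6. It was 22, 18, 19 and 80 without the spret females of litters 3, 4, 7 and 8, and 64 without the spret male of litter 4.

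Transgressive genes were then compared between the X chromosome and the autosomes. In embryo males 8 of 601 X-linked genes were transgressive, among them Nhsl2, the insulin signalling adaptor Irs4 (0.71 ± 0.18 and 0.62 ± 0.18), the receptor gene Gpr165 (0.61 ± 0.17 and 0.60 ± 0.17) and Syp (0.46 ± 0.14 and 0.77 ± 0.14), all above both parents, against 153 of 16776 autosomal genes (odds ratio 1.55, Fisher's exact 2-sided p = 0.275). The odds ratio was 3.17 (exact p = 0.00787, 8 of 599 genes against 75 of 16739) without the shallow library and 3.44 (exact p = 0.00171) without the spret male of litter 6. In embryo females limma called 0 of 601 X-linked genes, also 0 at an unadjusted p below 0.05, with edgeR and with DESeq2, against 2 autosomal genes (exact p = 1). Ldoc1 was the 1 X-linked gene among 597 in juvenile males (odds ratio 2.58, exact p = 0.445) and Gnl3l in females (1.98, exact p = 0.533). Adult males had F8a among 593 (0.71 ± 0.22 and 0.61 ± 0.22, odds ratio 1.62, exact p = 0.605) and adult females Gpr34 and the synapse adhesion gene Slitrk2 (-0.36 ± 0.11 and -0.51 ± 0.11, called in 14 of 38 alternatives, odds ratio 1.86, exact p = 0.393). The odds ratio in juvenile males was 7.35 (exact p = 0.00498) without the hybrid male of litter 3, and in adult males 3.44 (exact p = 0.0154) without that of litter 10.

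Imprinted genes, expressed from 1 parent's copy, are named by the series. In embryo males 4 of 72 imprinted genes tested were transgressive (Fisher's exact p = 0.00446). This test, as for the X, takes genes of the same animals as independent. Ppp1r9a, an actin-binding protein gene, lay above both parents (0.50 ± 0.14 against each). Below both lay the paternally expressed Peg12 (-1.50 ± 0.31 and -1.37 ± 0.31), the transporter gene Slc22a18 (-3.02 ± 0.73 and -2.85 ± 0.73, with hybrid males at 3.95 ± 4.79) and the signalling adaptor Gab1 (-0.45 ± 0.13 and -0.46 ± 0.13). The count was 2 without the shallow library, the dom male of litter 15 or that of litter 16. It was 1 with the fibroblast score and 0 by limma with the proliferation score, where 6 were called at an unadjusted p below 0.05. In adult females Plagl1, a paternally expressed zinc finger gene, was below both parents (-0.48 ± 0.10 and -0.34 ± 0.10), 1 of 68 genes (exact p = 0.147). The female total over the ages, 1, was 0 without the spret adult female of litter 3, with 7 calls at an unadjusted p below 0.05, and 2 without that of litter 8 or the hybrid juvenile female of litter 6. In embryo females, juveniles of both sexes and adult males limma, edgeR and DESeq2 each called 0 imprinted genes, and limma at an unadjusted p below 0.05 called 2 in embryo females, 2 in juvenile males, 1 in juvenile females and 2 in adult males. In juvenile males 23 of 31 paternally expressed genes lay below mid-parent (median -0.14), 1 called below, 2 above and 3 adjusted over the list alone (camera adjusted p over the 3 imprinted lists = 0.00771, and 0.15 with an estimated correlation).

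Male minus female differences, averaged over the genotypes, were led by the sex chromosomes. Besides Xist (-9.72 ± 0.29, -9.39 ± 0.29 and -10.19 ± 0.38 in embryos, juveniles and adults), the X-inactivation escape genes Eif2s3x (-0.51 ± 0.05, -0.52 ± 0.04 and -0.58 ± 0.07) and Kdm6a (-0.44 ± 0.08, -0.36 ± 0.06 and -0.52 ± 0.05) were higher in females. Among autosomal genes Zfp180 was higher in embryo males (0.90 ± 0.15), and in juvenile males Ddx4, a germ cell helicase gene (1.00 ± 0.16), and the zinc transporter gene Slc39a3 (0.34 ± 0.06). In adult females the nuclear receptor gene Nr5a2 (-0.98 ± 0.15) and Tac2, the neurokinin B gene of reproductive neurons (-0.41 ± 0.07), were higher. By limma 12 genes differed in embryos, 16 in juveniles and 16 in adults, and in adults 26 with litter as a random block. DESeq2 called 31, 22 and 24, and edgeR 13, 19 and 17.

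The 5 Y-linked genes tested were higher in males at each age (camera adjusted p = 4.36e-154, 2.44e-119 and 5.56e-126, 5 called on either basis). Of 14 escape genes 3, 5 and 5 were higher in females, 7 at each age adjusted over the list alone (adjusted p = 3.96e-26, 2.84e-31 and 1.72e-31). In embryos neuropeptide genes leaned to males, with 0 of 31 called on either basis (median 0.12, adjusted p = 0.00191, and adjusted p = 0.73 with an estimated correlation), as did fibroblast markers, 0 of 9 called on either basis (median 0.74, adjusted p = 0.00838, and adjusted p = 0.73 with an estimated correlation). In juveniles interferon-stimulated and antigen presentation genes leaned to females in 13 of 16 cases (median -0.15, adjusted p = 0.000259, and adjusted p = 0.176 with an estimated correlation), with 0 called on either basis. Astrocyte (median -0.06) and microglia markers (median -0.10) leaned to females with adjusted p = 0.0171 and 0.0416, and synaptic genes (median 0.07) and neuron markers (median 0.07) to males with adjusted p = 0.000171 and 0.0416, all with 0 called on either basis. With an estimated correlation these had adjusted p = 0.753, 0.762, 0.753 and 0.762. In adults respiratory chain genes leaned to males in 27 of 28 cases, 0 called on either basis (median 0.08, adjusted p = 1.09e-07, and adjusted p = 0.622 with an estimated correlation). Proliferation markers leaned to females, 0 called over all genes and 3 adjusted over the list alone (median -0.07, adjusted p = 0.0124, and adjusted p = 0.311 with an estimated correlation).

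The interaction asked whether the hybrid departure from mid-parent differs between the sexes. The X-linked lysosomal enzyme gene Gla (134588149 to 134601125) lay lower against mid-parent in hybrid males than in hybrid females at each age. The male minus female difference in departure was -1.26 ± 0.20 in embryos, -1.06 ± 0.11 in juveniles and -0.79 ± 0.13 in adults (limma adjusted p = 0.0104, 4.81e-06 and 0.0296). In embryos Gla stood at 561 ± 70.9 in hybrid males (n = 5) and 1380 ± 286 in hybrid females (n = 4), with 498 ± 85.9 in dom males and 2551 ± 620 in spret males. The other called gene was Clcn4 on chromosome 7 (7282309 to 7300851) in juveniles, with a difference of -0.83 ± 0.11 (adjusted p = 0.000183). Clcn4 lies on the X chromosome in Mus spretus and on chromosome 7 in laboratory mice. Hybrid males had 69.1%, 55.0% and 49.1% of the mean of the parents at the 3 ages, and hybrid females 103%, 97.6% and 77.8%.

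The 30 lists were tested for the same difference, with 0 members called on either basis in each list called. In embryos proliferation (median difference -0.49), fibroblast (-2.44) and microglia markers (-0.38) lay lower and synaptic genes (0.30), neuron markers (0.23), neuropeptides (0.19) and receptors (0.16) higher in hybrid males. Their adjusted p was 3.65e-06, 6.01e-05, 0.00995, 2.37e-07, 0.000589, 0.0364 and 0.0185, and adjusted p = 0.609 each with an estimated correlation. Without the shallow library the fibroblast difference was -1.19 (adjusted p = 0.00454) and neuropeptides were not called (adjusted p = 0.389). Without the hybrid female of litter 9 the fibroblast, proliferation, synaptic and neuron differences were -1.53, -0.32, 0.20 and 0.13, and receptors (adjusted p = 0.681) and neuropeptides were not called. In juveniles oligodendrocyte, thalamus, endothelial and fibroblast markers were called, and in 24, 28, 21 and 13 of 30 fits without 1 library (adjusted p = 0.726 each with an estimated correlation). In adults heat shock and stress genes, above mid-parent in hybrid females and near it in hybrid males, differed by -0.37 in 13 of 13 cases (adjusted p = 1.99e-09, and adjusted p = 0.097 with an estimated correlation). Oligodendrocyte markers (-0.30) and immediate early genes (-0.38, from -0.46 to -0.22 without 1 library) lay lower in males, with adjusted p = 1.39e-05 and 0.00182, and adjusted p = 0.606 each with an estimated correlation. These 3 held in every fit without 1 library. Red blood cell genes, ependymal and tanycyte markers and respiratory chain genes were called in 22, 29 and 24 of 30 such fits (adjusted p = 0.606, 0.606 and 0.775 with an estimated correlation). The respiratory chain difference of -0.09 was -0.03 (adjusted p = 0.713) without the spret male of litter 4, the adult litter that stood most apart.

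These were the calls of limma: 1 gene in embryos, 2 in juveniles and 1 in adults. Unadjusted p-values below 0.05 numbered 875, 560 and 528. With litter as a random block the counts were 8, 5 and 1, and with DESeq2 15, 6 and 1. The embryo count was 0 without the hybrid female of litter 9, 10 or 11 and 3 without the dom female of litter 16. The juvenile count was 5 without the spret male of litter 17. The adult count was 0 in 16 of the fits that left out 1 library, where unadjusted p-values below 0.05 numbered 425 to 580, and 2 without the hybrid male of litter 15.

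**Figure D2:**
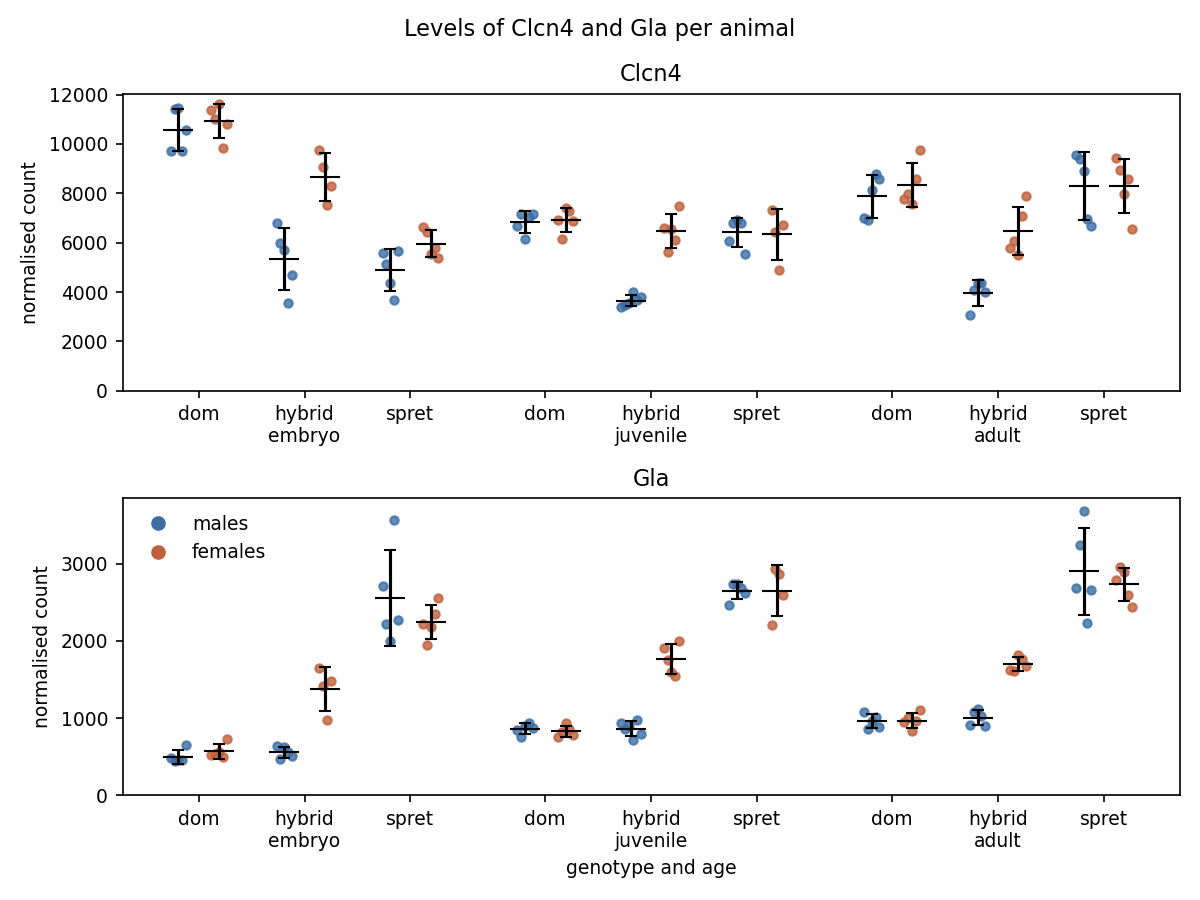
Normalised counts of Clcn4 and Gla in each animal by age, genotype and sex. Points are animals, and bars are means with standard deviations.

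Juveniles were compared with embryos over all genotypes and sexes. Myelin genes rose most: Mobp by 12.62 ± 0.22, from 21.1 ± 17.6 (n = 29) to 104630 ± 34038 (n = 30), Opalin by 10.97 ± 0.12, the sphingolipid enzyme gene Fa2h by 9.46 ± 0.18 and the sialidase gene Neu4 by 9.44 ± 0.20. Etnppl, an astrocyte enzyme gene, rose by 9.45 ± 0.18. The neural tube patterning gene Dbx1 changed by -8.18 ± 0.23, the RNA-binding protein gene Igf2bp1 by -7.66 ± 0.31, the homeobox gene Nkx2-3 by -6.71 ± 0.19, the axon guidance gene Draxin by -6.52 ± 0.09 and Zfp663 by -6.49 ± 0.31. Of 31 neuropeptide genes 30 rose, among them Hcrt (6.18 ± 0.16), Cartpt (3.90 ± 0.09) and Penk (2.54 ± 0.08), and the androgen receptor gene Ar rose by 4.10 ± 0.09. All 25 hypothalamic transcription factors fell, among them Sim1 (-1.98 ± 0.07). By limma 15388 of 18479 genes changed, 8292 up and 7096 down.

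Cell-type lists moved strongly between embryos and juveniles. All 13 oligodendrocyte markers rose (median 6.09, Plp1 by 7.54 ± 0.08, camera adjusted p = 1.09e-10, and 0.0072 with an estimated correlation) and 13 of 14 proliferation markers fell (median -2.76, Mki67 by -4.37 ± 0.14, adjusted p = 1.6e-06, and adjusted p = 0.0478 with an estimated correlation). Neuropeptides had a median of 1.99 (adjusted p = 3.87e-08, and adjusted p = 0.0599 with an estimated correlation) and 9 of 10 astrocyte markers rose (median 3.40, Gfap by 7.94 ± 0.19, adjusted p = 2.89e-05, and adjusted p = 0.0599 with an estimated correlation). Transcription factors had a median of -1.32 (adjusted p = 2.89e-06, and adjusted p = 0.144 with an estimated correlation). The steroid receptors and enzymes rose in 10 and fell in 3 of 14 cases (adjusted p = 0.0194, and adjusted p = 0.0841 with an estimated correlation). Hormone and neuropeptide receptors rose in 23 of 26 cases (adjusted p = 0.000185), microglia markers in 10 of 11 (adjusted p = 0.000124), oligodendrocyte precursor markers in 7 of 8 (adjusted p = 0.00727) and interferon-stimulated and antigen presentation genes in 14 of 16 (adjusted p = 0.0119). Cortex and hippocampus markers fell in 7 of 9 cases (adjusted p = 0.0119) and escape genes in 10 of 14 (adjusted p = 0.031), and each of these 6 lists had adjusted p = 0.163 with an estimated correlation.

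Of the remaining lists, 26 of 28 respiratory chain (adjusted p = 0.000438), 10 of 10 mitochondrial (0.0414) and 10 of 13 immediate early genes (0.00825) rose, 14 of 20 synaptic genes rose and 5 fell (0.0414), and 7 of 7 red blood cell genes fell (0.0194). In this order they had adjusted p = 0.418, 0.458, 0.318, 0.616 and 0.416 with an estimated correlation. In each list of this step as many members were called when adjusted over the list alone.

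Between juveniles and adults the myelin genes fell. Plp1 fell by 1.79 on the log2 scale (SE 0.08), Cldn11 by 2.17 (SE 0.32), Enpp6 by 1.94 (SE 0.24), Mal by 1.69 (SE 0.10) and the myelin basic protein gene Mbp by 1.58 (SE 0.08), and the mitotic spindle gene Fam83d fell by 3.10 (SE 0.13). The largest rises among genes with separated animals were Tomm34 (0.65 ± 0.04), Aldh9a1 (0.64 ± 0.03), the nuclear import gene Ipo5 (0.53 ± 0.04), Plekha3 (0.50 ± 0.03) and Kctd10 (0.46 ± 0.04). Of 13 oligodendrocyte markers 10 fell (median -1.40, adjusted p = 8.92e-14, and 0.00115 with an estimated correlation) and of 8 precursor markers 6 fell (median -0.72, adjusted p = 9.75e-06, and 0.0462 with an estimated correlation). Interferon-stimulated and antigen presentation genes rose in 11 of 16 cases, 12 adjusted over the list alone, among them Stat1 (0.34 ± 0.04), Tap1 (0.73 ± 0.09) and H2-D1 (0.78 ± 0.12) (adjusted p = 0.000474, and adjusted p = 0.0922 with an estimated correlation). Immediate early genes fell in 11 of 13 cases, among them Egr4 (-1.27 ± 0.21) (adjusted p = 0.00165, and adjusted p = 0.512 with an estimated correlation), and heat shock and stress genes in 5 of 13, among them Cdkn1a (-1.54 ± 0.11) (adjusted p = 0.0404, and adjusted p = 0.62 with an estimated correlation). Except for the interferon list, as many genes of each list were called adjusted over the list alone. By limma 9000 genes changed, 4685 up and 4315 down.

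The hybrid departure from mid-parent itself changed with age at some genes. From embryo to juvenile it rose for Fam227b (3.40 ± 0.39), the DNA repair gene Xrcc3 (1.46 ± 0.21), Ctsc (1.06 ± 0.16) and Brip1os (0.60 ± 0.09), with 135 genes called by limma (72 up, 63 down) and 34 with litter as a random block. From juvenile to adult it rose for Xkr6 (0.96 ± 0.14) and the receptor gene Prlhr (1.20 ± 0.22) and changed by -0.61 ± 0.09 for Fdft1 and -0.92 ± 0.15 for Ctsc, with 1281 genes called (712 up, 569 down) and 282 with the block. The first count was 68 and 425 without the hybrid embryo females of litters 19 and 9, 275 without the spret embryo male of litter 14, and 88 and 74 without the juvenile hybrid male and female of litter 1. The second was 682 and 770 without the adult hybrid male and female of litter 19, 851 without the dom adult male of litter 5 and 851 without the dom adult female of litter 6. It was 1949 without the spret adult male of litter 7 and 814 without the hybrid juvenile female of litter 1. DESeq2 called 360 and 1918 genes and edgeR 139 and 1378.

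Of the list calls above, those for Y-linked and escape genes between the sexes, oligodendrocyte markers at both age steps, proliferation markers from embryo to juvenile, precursor markers from juvenile to adult and mitochondrial genes in hybrid embryos held with an estimated correlation, the last in 10 of 29 fits without 1 library. Of the 75 list calls within an age, 39 held with the preset correlation in every fit without 1 library. Among these were all 8 against mid-parent in embryos. Over both sexes the others, with the fit that raised the adjusted p most, were mitochondrial genes between embryo parents (0.0714, without the shallow library) and respiratory chain genes between adult parents and against mid-parent (0.0869 and 0.103, without the spret male of litter 4). In adult hybrids transcription factors (0.0757, without the hybrid female of litter 13), astrocyte (0.110, the spret male of litter 7) and endothelial markers (0.103, the hybrid male of litter 12) were among them, and in juvenile hybrids oligodendrocyte markers (0.0823, the spret female of litter 16). Between the sexes these were embryo neuropeptides (0.0564, the hybrid female of litter 9) and fibroblast markers (0.135, that of litter 19) and adult proliferation markers (0.0659, the spret male of litter 2). In juveniles they were neuron markers and synaptic genes (0.636 and 0.0846, with medians of 0.02 and 0.03, the spret female of litter 13), astrocyte markers (0.218, the dom female of litter 11) and microglia markers (0.320, the hybrid female of litter 1).

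A list test on moderated statistics called 44 of 330 lists rather than 54. It lost neuropeptides and fibroblast markers between embryo sexes, neuron, astrocyte and microglia markers between juvenile sexes, proliferation markers between adult sexes, oligodendrocyte markers in juvenile hybrids and respiratory chain genes between adult parents. From embryo to juvenile it lost escape, red blood cell, interferon-stimulated and mitochondrial genes. It gained mitochondrial genes between juvenile parents (adjusted p = 0.00382) and in adult hybrids (0.0402). With the litter block the juvenile oligodendrocyte (0.0424) and astrocyte (0.0416) and adult proliferation lists (0.0499) were called again, heat shock genes in juvenile hybrids were gained (0.0383) and astrocyte markers in adult hybrids lost (0.0511). No estimated correlation was run here.

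Among the 11 comparisons between genotypes, sexes and ages, apart from the lists by sex and the interaction above, 8 lists had no call. Their lowest camera adjusted p-values were 0.0955, 0.177 and 0.192 for paternally expressed, maternally expressed and tissue-dependent imprinted genes and 0.0788 to 0.127 for ependymal and tanycyte, choroid plexus, pituitary, thalamus and striatum markers.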

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

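The tests of the shallow library, the fibroblast and proliferation scores, the thalamus and striatum score, a batch behind litter 17 and 1 active copy of Clcn4 were chosen only after the result was seen. Of 108 groups of animals examined, 15 had an animal far from the others, against about 1 in 20 groups that chance flags.

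Groups differed from each other in 3 kinds of result. X-linked positions of hybrid males exceeded those of hybrid females by 0.477 in embryos, 0.576 in juveniles and 0.563 in adults, by an exact permutation test. The hybrid departure from mid-parent differed between the sexes for Gla (-1.26, -1.06 and -0.79 at the 3 ages) and for Clcn4 in juveniles (-0.83), by the interaction test. It differed between ages at 135 genes from embryo to juvenile and at 1281 from juvenile to adult.

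Single animals lay far from their groups as follows. In total counts these were the dom juvenile female of litter 11 (59325432), the hybrid embryo female of litter 19 (62937810), the hybrid juvenile female of litter 2 (63343631), the spret adult male of litter 4 (58097896) and the spret embryo female of litter 6 (57632862). The hybrid embryo male of litter 20 stood apart in total count (6514390), genes with a count (15013), autosomal position (-0.0995) and fibroblast score (-4.70). Autosomal position was also low in the hybrid embryo female of litter 11 (0.187). The spret embryo male of litter 6 had a neuron score of -0.969 and a proliferation score of 0.716. Pnma2 stood at 1556 in the hybrid embryo female of litter 9, Gla at 648 in the dom embryo male of litter 8, and Spesp1 at 7.64 in 1 dom adult and 0 in the other 9.

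Embryo males had 161 transgressive genes and embryo females 2. Without the shallow library the counts were 83 and 2, which argues against low depth in 1 library as the whole cause. With the fibroblast score in the fit limma called 3, the median smaller fold change of the 161 genes going from 0.85 to 0.39 (standard errors 0.251 and 0.246), and with the proliferation score it called 0 (84 at an unadjusted p below 0.05, no other tool run), the median going to 0.28 (standard error 0.278). Random lists matched on expression lowered the count as far in 13 of 100 cases for fibroblasts and 0 for proliferation, but lists also matched on the difference between hybrid and parent males did so in 78 and 37 of 100, so neither connective tissue nor proliferating cells or maturity can be told apart from any other difference between these libraries. All 9 fibroblast and 14 proliferation markers are also expressed in the parent embryos, the most abundant being Col1a2 (1919 ± 939 in hybrid males, 9809 ± 8501 in parent males) and Sox2 (11314 ± 733 and 13443 ± 3066), and an effect of hybrid genotype on male embryos stays open, untested apart from these scores.

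In juvenile spret litter 17 both siblings lay beyond every other juvenile at 2285 genes (1249 above, 1036 below), against 499 for the next litter and a median of 284. Thalamus markers were higher in this litter (7 of 8, median 1.14) and so were striatum markers (6 of 8, median 0.57), all 8 of each also being expressed in the other spret juveniles, with Rora at 6325 ± 1465 against 5772 ± 3636 and Ppp1r1b at 6334 ± 1352 against 3658 ± 843, and cortex and hippocampus markers were higher too (8 of 9, median 0.32) and microglia (2 of 11 higher, median -0.53) and red blood cell genes (1 of 6 higher, median -0.77) lower. After the thalamus and striatum score was regressed out 1362 genes still lay apart, which argues against thalamus or striatum in the dissection as the whole cause and leaves other tissue open. No batch label exists, so for these 2285 genes a library batch cannot be told apart from the litter. A biological difference of this litter was not tested.

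Hybrid males had 49.1% of the parental mean of Clcn4 in adults and 55.0% in juveniles. In embryos, where spret had less than dom, they had 69.1% of the mean and 50.5% of dom. Levels near 50% of dom are consistent with 1 active copy in males, as for a gene on the X in spret and on chromosome 7 in dom, since hybrid males lack a spret X. Of 14 neighbouring genes within 1 Mb on chromosome 7 the median departure in hybrid males was -0.00416 (-0.52 to 2.79), which argues against a change of the whole region. Reads of the copies cannot be separated in these files, so a copy-specific test was not possible.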

How the results depend on the processing

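The tests with both siblings of litter 17 or 19 left out and with the fibroblast or proliferation score in the fit were chosen only after the result was seen. Counts that moved by less than 1.5 times and values that kept their direction and their side of the threshold are left out below, and the cause was not tested except where named.

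With a pseudocount of 8, autosomal positions were 0.156 in embryo females and 0.124 in juvenile males, embryo females had 1 transgressive gene and the juvenile male minus female count was -12. Without the filter, which tests more genes, 2 genes differed between the sexes in hybrid departure in embryos, transgressive genes numbered 106 and 5 in embryo males and females (difference 101), and the X odds ratio was reversed in juvenile (0.854) and adult (0.773) males. Quantile normalisation gave autosomal positions of 0.173 (embryo females), 0.116 (juvenile males) and 0.151 (adult males), differences of -11 in juveniles and -9 in adults, an X odds ratio of 0.963 in adult females, reversed, and 0 adult interaction genes by limma (523 at an unadjusted p below 0.05).

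With edgeR the juvenile difference was 0 and the X odds ratio in adult males 0.484, reversed. DESeq2 called 829 embryo genes against mid-parent, 360 whose departure changed from embryo to juvenile, 31 between the sexes in embryos, and 15 and 6 interaction genes in embryos and juveniles. Its transgressive counts were 325 and 8 in embryos, 26 and 38 in juveniles and 51 and 70 in adults, males first, with differences of 317 in embryos and -12 in juveniles, and its X odds ratio in embryo males was 1.70, past the threshold.

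With litter as a random block the counts against mid-parent were 183, 573 and 958, those of departures that changed with age 34 and 282, those of interaction genes 8 and 5 in embryos and juveniles, and 26 adult genes differed between the sexes. The adult difference in transgressive genes was -6, and the X odds ratio in juvenile males 0.692, reversed. The block changed no other call of these counts. As a fixed effect in litters with both sexes it gave 16, 15 and 17 genes between the sexes.

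A minimum fold of 1.5, which passes fewer genes, gave 7 and 10 transgressive genes in juvenile males and females and 15 in adult females, differences of -3 in juveniles and 4 in adults, the latter reversed, an X odds ratio of 0.776 in embryo males, reversed, and 2 imprinted genes in males and 0 in females by limma (3 at an unadjusted p below 0.05). When each sex was fitted alone, with fewer libraries per fit, embryo males had 35 transgressive genes and a difference of 32, juvenile females had 14, the differences were 9 in juveniles, reversed, and -28 in adults, and males had 2 imprinted genes. The X odds ratios were then 6.59 in juvenile males, past the threshold, and 0.978 and 0.902 in juvenile and adult females, reversed. At 4 animals per group the median difference was 55 in embryos and 2.5 in adults, the latter reversed. The background with a mean of at least 100 changed no X call.

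Without litter 19 adults had 599 genes against mid-parent, 0 interaction genes by limma (484 at an unadjusted p below 0.05), 12 and 20 transgressive genes in males and females, a difference of -8 and an X odds ratio of 0.695 in females, reversed. Without litter 17 juveniles had 4 interaction genes, an autosomal position of 0.170 in males and a difference of 0. Without both litters 192 genes changed departure from juvenile to adult. With the fibroblast score limma called 206 embryo genes against mid-parent, 0 interaction genes (358 at an unadjusted p below 0.05), 3 and 1 transgressive genes, a difference of 2 and 1 imprinted gene in males. With the proliferation score it called 170 against mid-parent, 0 interaction genes (271 unadjusted), 0 transgressive genes in males (84 unadjusted), a difference of -2, reversed, and 0 imprinted genes in males (6 unadjusted). The smaller fold change of Col3a1 in embryo males turned to 0.087 with the fibroblast score, and that of Abcc8 to -0.074 with the proliferation score.

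Leaving out each library in turn gave these ranges, in the order embryo, juvenile and adult. Genes between the parents numbered 6920 to 7828, 9029 to 9673 and 8692 to 9365, against mid-parent 242 to 627, 628 to 1002 and 1207 to 3501, between the sexes 12 to 13, 15 to 19 and 15 to 18, and in the interaction 0 to 3, 2 to 5 and 0 to 2. Transgressive genes numbered 52 to 201, 6 to 21 and 12 to 69 in males and 1 to 3, 12 to 45 and 17 to 94 in females, with differences of 51 to 200, -28 to 6 and -58 to 19. X odds ratios ran from 0.713 to 3.44, 1.24 to 7.35 and 0.624 to 3.44 in males and from 3.98 to 9.33 (counts of 0 plus offset), 0.767 to 4.60 and 0.454 to 2.32 in females. Autosomal positions were 0.111 to 0.193, 0.139 to 0.170 and 0.165 to 0.214 in males and 0.195 to 0.234, 0.127 to 0.169 and 0.147 to 0.192 in females. X positions were 0.713 to 0.808, 0.778 to 0.921 and 0.877 to 0.959 in males and 0.184 to 0.335, 0.221 to 0.353 and 0.275 to 0.402 in females. From embryo to juvenile 15310 to 15429 genes changed and from juvenile to adult 8811 to 9267, and departures at 68 to 425 and 682 to 1949. Imprinted transgressive genes numbered 2 to 5 in males and 0 to 2 in females.

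Of 322 fold changes and pairs of them followed gene by gene, a pseudocount of 8 gave 319, DESeq2 316 and edgeR 310 with the same direction and call, quantile normalisation 308, the litter block 292 and no filter 295, and the others had the same direction and were not called. Of those to which the setting applies, 32 of 50 kept their call with each sex fitted alone, 62 of 86 without litter 19, 76 of 85 without litter 17, 82 of 82 without both and 34 of 61 with either marker score, which reversed 1 each. Leaving out 1 library lost the call in 501 of 14429 cases. Of the 322, 10 held in under 50% of their alternatives, those given in the comparisons above and Plagl1 against mid-parent in embryos (14 of 37). The total count of the shallow library is 9.56 times below the median, so genes near the floor were not detectable in it.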

Other observations

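The test of each hypothesis in this part was written before its result was seen, except the comparisons of litters and siblings, the correlation of the marker scores, the swaps of sex within litters and the exchanges of residuals, which were tests chosen only after the result was seen. In adult hybrids 5 of 26 hormone and neuropeptide receptors lay above mid-parent and 0 below (6 adjusted over the list alone, camera adjusted p = 0.162).

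Juvenile hybrid females ran from 0.00781 to 0.533 in X-linked position. Under unequal X inactivation separate X-linked gene sets should rank females alike. Positions from alternate X-linked genes, taken as deviations from the mean of each age, correlated across the 14 hybrid females (r = 0.687, permutation p = 0.00762, Benjamini-Hochberg value 0.0190 over 5 relations, rho = 0.692 with permutation p = 0.00775, r = 0.662 without the 2 farthest animals). The X position was not seen to follow the autosomal position (r = 0.190, permutation p = 0.509, Benjamini-Hochberg value 0.509, rho = 0.187 with permutation p = 0.522, r = 0.242 without the 2 farthest), which argues against animals that differ on all chromosomes. In the 16 hybrid males, which have 1 X, alternate sets gave r = 0.355 (permutation p = 0.179, Benjamini-Hochberg value 0.298, rho = 0.103 with permutation p = 0.709, r = -0.046 without the 2 farthest). Juvenile litters 1 and 9 were lowest in both sexes, embryo litter 9 in males only. Unequal X inactivation and a litter effect both stay open as hypotheses. The correlations of the sexes were not compared.

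Fibroblast and proliferation scores correlated across the 29 embryo libraries, as deviations from group means (r = 0.625, permutation p = 0.00031, Benjamini-Hochberg value 0.00155, rho = 0.536 with permutation p = 0.00336, r = 0.600 without the 2 farthest), so fits with either score are not independent of the other. Siblings resembled each other: the mean correlation across genes between siblings, as deviations from group means, was 0.217 (40 pairs, 36 above 0) against -0.048 for animals of different litters (180 pairs, 75 above 0). In adults the 2 hybrids of litter 19 had higher thalamus (8 of 8, median deviation 0.44) and striatum markers (7 of 8, 0.29) than the other 8 and lower red blood cell genes (0 of 6 higher, -1.41). Deviations of litters 19 and 17 correlated (r = 0.353 over 13117 genes, which are not independent). Without litter 12 adults had 970 genes against mid-parent.

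Random splits of the animals, 100 with the real one included, tested chance. Shuffling genotype excluded chance for genes between the parents (embryo 7331, highest other 1, juvenile 9354 and 3790, adult 9183 and 3). Such splits mix the parental species within a group, so they say little about counts that set hybrids against parents: against mid-parent 372 and 663, 895 and 1, 2538 and 0 (3, 1 and 1 splits as large), transgressive in males 161 and 1, 17 and 1, 27 and 1 and in females 2 and 0, 23 and 0, 41 and 0, and imprinted and transgressive 4 and 0 in males and 1 and 0 in females (1 split as large in each). Shuffling age excluded it for the age steps (15388 and 6845, 9000 and 7424). It mixes ages, so it says little about departures that changed (135 and 6311, 1281 and 2). Shuffling sex excluded chance for genes between the sexes (12 and 619, 16 and 147, 16 and 1714) and for the juvenile interaction (2 and 3). It was not excluded for the embryo and adult interaction (1 and 1354, 1 and 4) or for the male minus female number of transgressive genes (159 and 493, -6 and 145, -14 and -1452), where 6, 88 and 93 splits were as large. The highest splits called several times the real count for departures changed from embryo to juvenile and for genes between the sexes, though the median split called 0, which points to sample structure. The numbers pair siblings, and the splits that part every sibling pair, as the real one does, had lower maxima: 2, 3 and 8 genes between the sexes, 2, 3 and 2 in the interaction and differences of 90, 28 and -124. Among these chance was excluded for genes between the sexes and for the embryo difference of 159, but not for the interaction or the differences of -6 and -14.

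The residuals of whole litters were also exchanged between litters of the same make-up, in 100 draws with the real one included, on means without the effect tested. Chance was excluded for genes between the parents (7331 and 2629, 9354 and 1481, 9183 and 2939) and against mid-parent (372 and 1184, 895 and 2407, 2538 and 2185, with 4, 2 and 1 draws as large). For transgressive genes it was not excluded in males (161 and 509, 17 and 141, 27 and 575, with 11, 25 and 15 draws as large), in embryo and juvenile females (2 and 58, 23 and 869, with 61 and 37) or for the male minus female number (159 and 509, -6 and -863, -14 and 557, with 11, 61 and 24). It was excluded for adult females (41 and 37) and for the 4 imprinted genes of embryo males (2 draws as large, highest 5), and not for the 1 of adult females (7 as large, highest 1). Draws that call several times the real count point to litters that stand apart.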
